A study of Mus musculus with 32 samples.

How the data were processed

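RNA of mouse embryonic fibroblasts was measured by RNA sequencing in 32 samples. Per the labels, total RNA was taken up in TRIzol and 1 µg of it went into each library, made with version 2 of Illumina's TruSeq RNA kit. The 4 cell lines were an ATM knock-out line with its wild-type line (wtATM) and an ATMIN knock-out line with its own wild-type line (wtATMIN). Each line was treated with 1 µM aphidicolin (APH) or with DMSO for 4 h or 24 h, which gives 16 groups of 2 samples. The tables name treatments AT and UT, which were read as APH and DMSO because only these treatments appear in the labels.

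The authors deposited 1 table of raw read counts per Ensembl gene, with 39017 genes and no row for reads outside genes. Per the submitters' processing notes, Bowtie2 2.4.0, TopHat2 2.0.13 and DESeq2 1.6.3 were used on build mm10. The notes give no counting tool, strand setting or Ensembl release, so reads of overlapping or antisense genes could not be told apart. The authors also deposited 10 comparison tables with shrunken log2 fold changes and adjusted p-values, in the form that DESeq2 writes, per the file headers. In all 10 tables the columns of group means carry the name of the other group, as the columns of single samples show, so the group means were not used. The same tables hold 120 columns of normalised values for single samples, which were not used. Symbols came from the authors' tables for 16476 genes and from GENCODE release M21 on GRCm38 (the same build as mm10) for 21380 more. No symbol was found for 1161 genes, and 37607 genes had a position.

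The total count per sample ran from 9321329 to 21020662. Counts were tested with edgeR 4.0.16 in R 4.3.3. Filtering by group (filterByExpr) kept 18484 genes and libraries were scaled by TMM. Then 1 quasi-likelihood model (estimateDisp, glmQLFit with robust set, glmQLFTest) was fitted to all 32 samples in 16 groups. The common biological coefficient of variation was 0.0643. A group of 2 leaves little to estimate its own spread, so all groups shared 1 estimate. P-values were adjusted by Benjamini-Hochberg within each of 28 comparisons, and a gene was called at an adjusted p under 0.05. These were APH against DMSO per line and time, knock-out against its wild type per condition, the difference of APH responses between knock-out and wild type, the difference of APH responses between 24 h and 4 h, and the wild-type lines against each other. CPM values are counts scaled to the TMM-normalised library size with their SD over 2 samples, or over 8 samples where a whole line is described. A log2 fold change is followed by its standard error from the fit. Where a line had no read of a gene, the fold is a lower bound set against 3 counts over the line's 8 libraries. For 1 to 3 reads the ratio is given with its exact 95% counting interval. Both divide the mean CPM of the higher line by the other line's reads (or 3 counts) over its summed library size. Floors and intervals cover counting error only.

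Genes are named by a rule set with the tests, the groups and the 22 gene lists before the data were examined. The rule takes Atm, Atmin, Dynll1, Dynll2, Npat, Cdkn1a, Mdm2, Trp53, Chek1, Dpysl2 and H2afx in every comparison. It then takes genes with a mean logCPM of at least 1 and a symbol that is no clone name. For APH these are the 10 largest and 10 smallest mean changes among genes called alike in all 4 lines. For each knock-out they are the 10 largest and 10 smallest among genes called alike in all 4 conditions. For a difference of responses they are the 5 largest and 5 smallest called, and for the wild-type lines the 5 largest and 5 smallest called at both times. For each list described it takes up to 4 members with the smallest p. The text leaves out members for length but keeps this order.

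The lists cover p53 targets, replication and E2F targets, G2/M and mitosis genes, replication-dependent histones, homologous recombination and Fanconi genes, checkpoint kinases, cholesterol synthesis, interferon-stimulated genes, NF-kB inflammatory genes, immediate-early and AP-1 genes, the integrated stress response, NRF2 targets, matrix and fibroblast genes, lysosome and autophagy genes, posterior Hox genes and sex-linked genes. Markers of epithelial, blood, endothelial, muscle, neural and adipocyte cells were included because embryo cultures could hold such cells. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 588 pairs of list and comparison. Camera with an estimated correlation and fry were alternatives. The adipocyte list had only 4 tested genes and was not tested as a list. Genes near Atm and Atmin were compared with Fisher's exact test, two-sided.

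Alternatives were RLE size factors, library size only, no filter on low counts, DESeq2 1.42.0, a replicate block, a fit to the compared groups alone and a fit without each library in turn (32 fits). Without a library, its group's remaining sample is assumed to vary like the other groups. Alternatives added after the data were seen were lists without either ATM knock-out APH 4 h library, the shared APH response without that line, the interaction without the most abundant genes of those libraries, and knock-out calls after taking off the medians of chromosomes or of 20 Mb bins. Lists without a library were adjusted over the 21 lists of a comparison. With chromosome medians taken off, a gene still differed if it did so by over 1.96 standard errors in all 4 conditions, unadjusted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

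The model was tested on simulated counts with 200 changed genes. For APH in wtATM at 24 h it called 33 of 67 genes changed 1.5-fold, 44 of 67 changed 2-fold and 52 of 66 changed 4-fold, and 9 unchanged genes were called among the 18266 tested. For the ATM interaction at 24 h it called 31.3%, 56.7% and 69.7% of these sizes. In the list test the moved list passed, and 0 of 20 lists that were not moved did. The genes were drawn independently, each with its fitted spread, which was the same in all groups. The simulation therefore does not test lists of correlated genes or groups of unequal spread.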

Results

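RNA was sequenced from 4 mouse embryonic fibroblast lines: an ATM knock-out line and its wild-type line (wtATM), and an ATMIN knock-out line and its wild-type line (wtATMIN). ATM is a kinase of the DNA damage response, and ATMIN is a zinc finger protein that binds ATM. Each line was given aphidicolin (APH, 1 µM), an inhibitor of the replicative DNA polymerases, or DMSO alone, for 4 h or 24 h, with 2 samples in each of the 16 groups. Values for the 4 lines are given in the order wtATM, ATM knock-out, wtATMIN and ATMIN knock-out. The labels do not say whether the 2 samples of a group are separate cultures. Each p-value therefore measures only spread between samples within groups, estimated over all 16 groups together. There is 1 line per knock-out, so genotype and line cannot be told apart.

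The total count per sample ran from 9321329 to 21020662 reads in genes. After a filter on low counts 18484 genes were tested. Principal components of the 32 samples separated cell lines first (29.5% and 28.7% of the variance) and then 4 h from 24 h (15.3%). The ribosomal sequence Gm42418 took between 13535 and 83079 CPM (reads scaled to library size) in the 4 h libraries and between 254 and 5933 in the 24 h libraries, DMSO samples included. The library of ATM knock-out APH 4 h replicate 2 was the shallowest, at 9321329 reads. It had reads on 457 of 1640 olfactory and vomeronasal receptor genes, which fibroblasts do not use, against 174 in replicate 1 and 22 to 106 in the other 30 libraries. Its correlation with its replicate was 0.9874, against 0.9938 to 0.9975 elsewhere. Replicate 1 had the 83079 CPM of Gm42418, against at most 37651 in the other 30 libraries, and a TMM factor of 0.8492 against at least 0.9123.

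**Figure D1:**
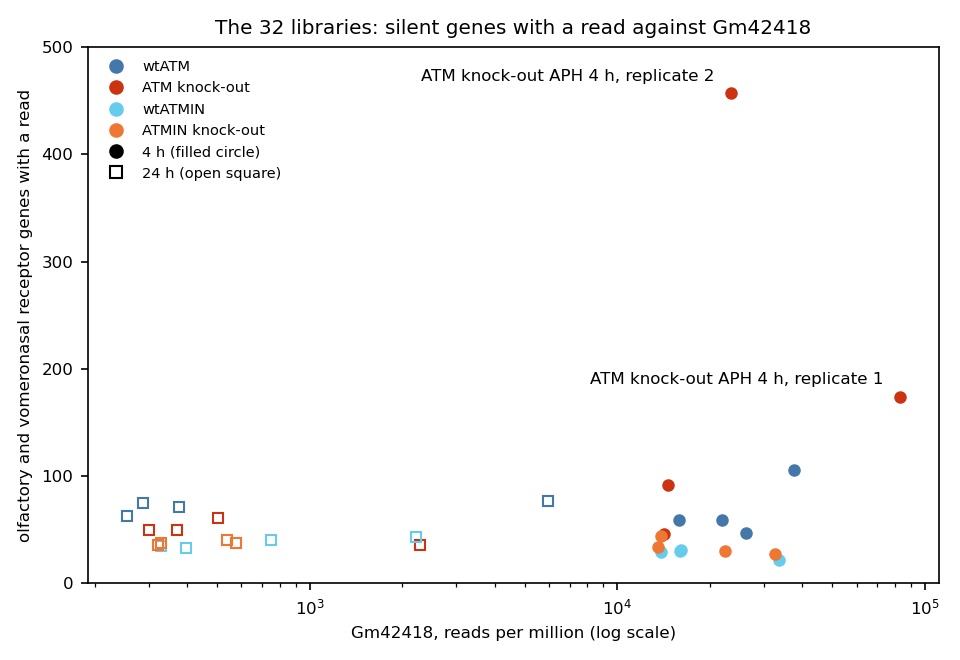
Each point is 1 of the 32 libraries. The horizontal axis is Gm42418 in CPM (log scale) and the vertical axis the number of olfactory and vomeronasal receptor genes with a read; ATM knock-out APH 4 h replicate 2 stands apart with 457 and replicate 1 with 83079 CPM of Gm42418, and the 4 h libraries lie at higher Gm42418 than the 24 h libraries.

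The targeted genes were read first. Atmin (ENSMUSG00000047388; mm10 chromosome 8, 116943393 to 116960445) was at 4.78 ± 0.105, 4.10 ± 0.456, 5.50 ± 0.436 and 6.71 ± 0.0786 CPM (SD, n = 2) in the ATMIN knock-out line in DMSO 4 h, APH 4 h, DMSO 24 h and APH 24 h. The same gene was at 25.5 ± 0.726, 31.9 ± 1.46, 20.6 ± 0.214 and 28.5 ± 1.78 CPM in wtATMIN. The knock-out was lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in each condition (log2 between −2.97 ± 0.13, adjusted p = 3.26e-20, and −1.90 ± 0.12, adjusted p = 1.55e-15). Dynll1, a known transcriptional target of ATMIN, was lower with it (adjusted p from 3e-26 to 1.24e-20): 50.3 ± 1.89, 59.0 ± 3.59, 29.6 ± 1.04 and 45.5 ± 1.42 CPM in the knock-out against 211 ± 22.5, 193 ± 3.88, 197 ± 6.55 and 205 ± 0.172 CPM in wtATMIN. Atm (ENSMUSG00000034218; mm10 chromosome 9, 53439149 to 53536740) was at 21.6 ± 5.28, 38.5 ± 5.68, 33.2 ± 0.0394 and 43.9 ± 2.29 CPM in the ATM knock-out line. In wtATM it was at 51.1 ± 1.52, 53.8 ± 12.9, 64.7 ± 0.644 and 47.7 ± 6.51 CPM. The knock-out line was lower by −1.24 ± 0.16 in DMSO at 4 h (adjusted p = 5.92e-07) and by −0.96 ± 0.15 in DMSO at 24 h (adjusted p = 6.4e-06). With APH the difference was −0.51 ± 0.16 at 4 h (adjusted p = 0.00784) and −0.12 ± 0.15 at 24 h (adjusted p = 0.509). The 4 h call was lost without wtATM APH replicate 1 (−0.23) or ATM knock-out APH replicate 1 (−0.37). The allele is not given in the labels, and a count over the whole gene does not check a deletion within it.

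**Figure D2:**
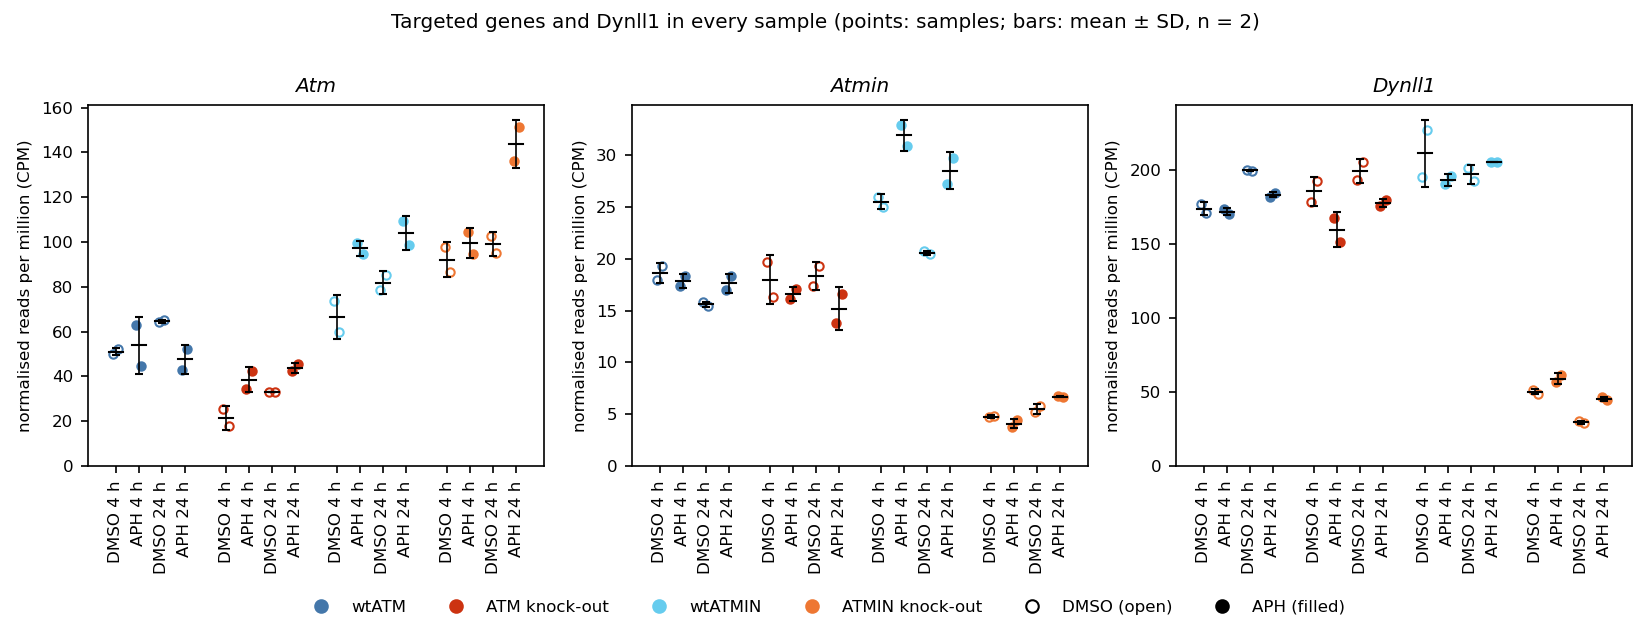
Normalised CPM (vertical axes) of Atm, Atmin and Dynll1 in every sample, by line and condition (horizontal axes); bars give mean and SD of 2 samples. Atmin stays at 6.71 CPM or less in the ATMIN knock-out groups and Dynll1 at 59.0 CPM or less, while Atm transcripts remain in the ATM knock-out line at 21.6 to 43.9 CPM.

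After 4 h of APH, mitotic genes fell in all 4 lines, and single genes rose or fell alike in them. Ptpn22, a phosphatase of immune signalling, rose by 1.42 ± 0.30, 2.96 ± 0.41, 1.36 ± 0.21 and 1.85 ± 0.27 (log2; wtATM no longer passed without DMSO replicate 2, at 1.31). Has2, a hyaluronan synthase, rose by 0.64 ± 0.10, 1.85 ± 0.13, 1.64 ± 0.14 and 2.17 ± 0.13, and Ptgs2, the inducible cyclooxygenase, by 1.01 ± 0.08, 1.36 ± 0.08, 1.58 ± 0.08 and 1.37 ± 0.08. H1f0, a linker histone, changed by −2.18 ± 0.07, −1.61 ± 0.08, −2.01 ± 0.07 and −1.72 ± 0.07. Cdc20, which activates the anaphase-promoting complex, changed by −1.24 ± 0.07, −1.38 ± 0.07, −1.48 ± 0.07 and −1.65 ± 0.07. Among the genes fixed in advance, H2afx fell in each line (−0.69 ± 0.09, −1.43 ± 0.11, −1.08 ± 0.09 and −0.82 ± 0.09). Chek1 differed in direction, with −0.52 ± 0.13 in wtATM (adjusted p = 0.00929) and 0.51 ± 0.12 in the ATM knock-out (adjusted p = 0.000897). These Chek1 calls were lost without wtATM DMSO replicate 2 (−0.37) or APH replicate 1 (−0.49), and without ATM knock-out APH replicate 2 (0.31). Dpysl2 passed in no APH comparison.

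G2/M and mitosis genes fell at 4 h: 36, 29, 36 and 40 of 42 were lower and 0 higher (41, 29, 40 and 42 lower and 0, 1, 0 and 0 higher adjusted over the list alone; adjusted p between 3.4e-119 and 6.65e-29). Plk1, a mitotic kinase, fell in each (−1.20, −1.34, −1.32 and −1.63, each ± 0.07). Cholesterol synthesis genes fell too, with 21, 21, 19 and 14 of 25 lower and 0, 0, 0 and 1 higher (22, 22, 21 and 16 lower over the list alone), and Insig1 at −0.81 ± 0.07 in wtATM. The ATMIN knock-out call had an adjusted p = 0.128 with an estimated correlation. Of 44 replication histones, 38, 27 and 33 fell in wtATM, wtATMIN and the ATMIN knock-out (43, 38 and 41 over the list alone), while the list did not pass in the ATM knock-out. With an estimated correlation the histone adjusted p was 0.0111, 0.129 and 0.162. Paralogous histone genes share reads. Gm42418 also differed between replicates at 4 h (37651 and 15892 CPM in wtATM DMSO), and library content was not tested apart from the histone change. In the ATM knock-out the histone median was −1.18 without APH replicate 1 and 0.36 without replicate 2. Without ATM knock-out APH replicate 1, 19 histones fell in that line and the list passed (adjusted p = 0.000182), and without replicate 2 it did not (adjusted p = 0.236).

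Replication and E2F target genes rose at 4 h: 7, 25, 30 and 37 of 47 were higher and 0, 5, 0 and 0 lower (7, 27, 34 and 43 higher over the list alone; wtATM adjusted p = 0.177 with an estimated correlation). Ccne1, cyclin E1, rose by 0.92 ± 0.08 in wtATM, 1.14 ± 0.08 in wtATMIN and 1.6 ± 0.08 in the ATMIN knock-out. Homologous recombination and Fanconi genes rose, with 2, 19, 18 and 17 of 35 higher and 0, 3, 0 and 1 lower (3, 20, 21 and 20 higher over the list alone; wtATM adjusted p = 0.183 with an estimated correlation). NF-kB inflammatory genes rose, with 9, 10, 8 and 18 of 28 higher and 0, 1, 3 and 0 lower (11, 12, 9 and 19 higher over the list alone; adjusted p between 1.29e-26 and 0.0016). Immediate-early and AP-1 genes rose in 3 lines, with 11, 11 and 15 of 25 higher in wtATM, wtATMIN and the ATMIN knock-out (12, 13 and 17 over the list alone). In the ATM knock-out the list passed as higher without APH replicate 2 (8 higher, 3 lower; adjusted p = 0.00931) and did not pass without replicate 1 (4 higher, 11 lower; adjusted p = 0.227). The wtATMIN call had an adjusted p = 0.129 with an estimated correlation. Ctgf, a secreted matricellular protein, rose by 1.27 ± 0.08, 1.12 ± 0.07 and 1.31 ± 0.07 in these lines. Lysosome and autophagy genes fell in wtATMIN and the ATMIN knock-out (14 and 15 of 30 lower, 23 and 23 over the list alone). With library size as the only scaling they also passed in the ATM knock-out (adjusted p = 0.0296), as they did without its APH replicate 1 (adjusted p = 0.0445). Checkpoint kinase genes passed as lower in wtATM (4 of 25, 5 over the list alone; adjusted p = 0.32 with an estimated correlation). In the ATM knock-out, p53 targets passed as higher (13 higher and 6 lower of 35, as over the list alone; adjusted p = 0.0593 with an estimated correlation).

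The numbers of genes called at 4 h were 1032, 5433, 2773 and 3768, with 521, 2586, 1341 and 1753 of them higher. Library size alone gave 625 higher and 371 lower in wtATM, and 1895 higher and 3759 lower in the ATM knock-out, against 511 and 2847 lower with TMM. Without 1 library the wtATM count was 528 to 570 for DMSO replicate 1 or 2 or APH replicate 2. The ATM knock-out count was 2689 without DMSO replicate 2 and 2392 without APH replicate 2. The wtATMIN count was 1408 without DMSO replicate 2 and 1432 and 1717 without APH replicates 1 and 2. The ATMIN knock-out count was 2270 without DMSO replicate 2 and 2337 without APH replicate 2. With the spread taken from the compared groups alone the counts were 1226, 1136, 2197 and 5021, so the ATM knock-out went from the most calls to the fewest. In all 4 lines 82 genes rose and 165 fell, where independent lists of these sizes would share 0.502 and 0.665 genes. With the compared groups alone 49 rose and 96 fell. Without the ATM knock-out line, 188 rose and 259 fell in the other 3 lines. Over all 4 lines, 510 genes were called up in a line and down in another.

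**Figure D3:**
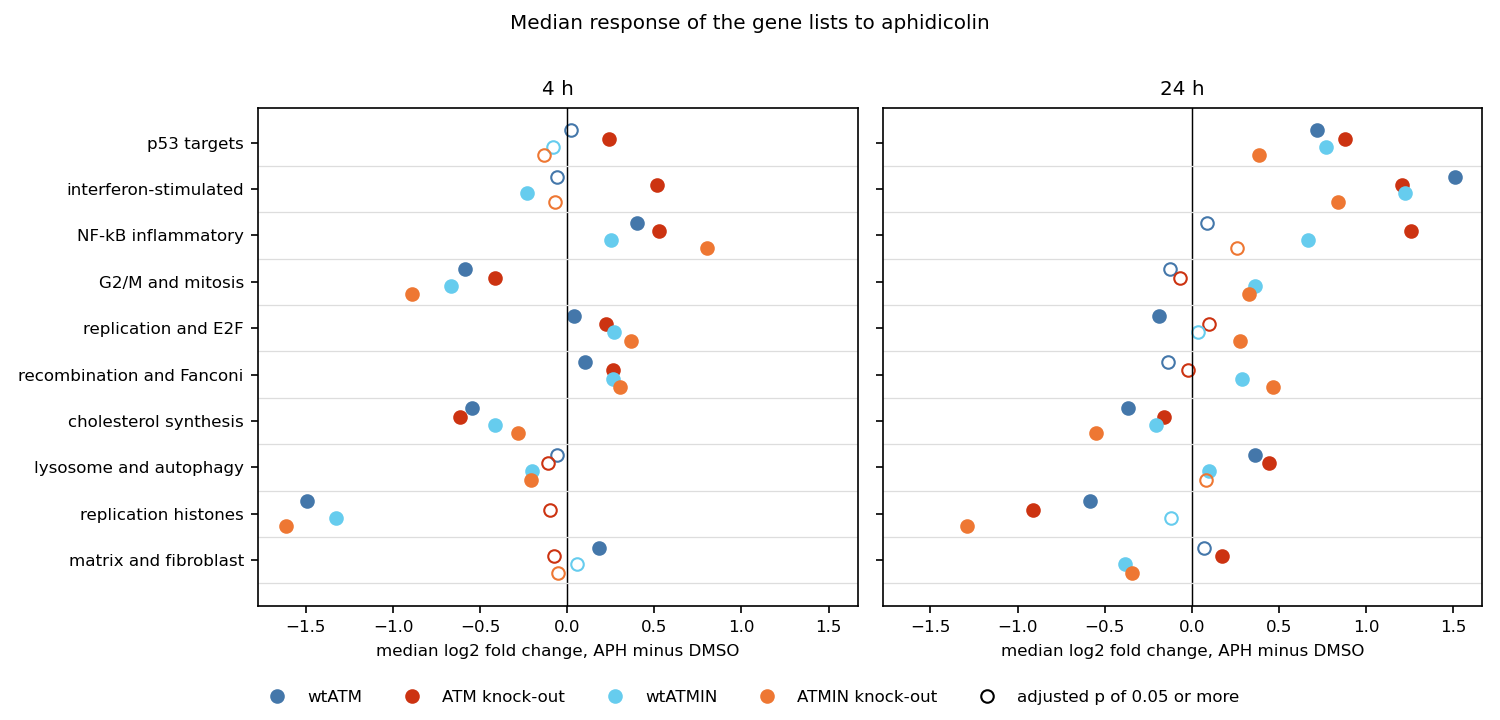
Median log2 fold change (APH minus DMSO, horizontal axes) over the tested members of 10 gene lists in each line at 4 h and 24 h; filled points passed camera at an adjusted p under 0.05. Mitosis medians lie between −0.42 and −0.89 at 4 h, and p53 target medians between 0.39 and 0.88 at 24 h.

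After 24 h of APH, p53 target genes and interferon-stimulated genes rose in all 4 lines. Cdkn1a, which encodes the p21 cell cycle inhibitor, rose by 1.88 ± 0.12, 1.64 ± 0.13, 2.4 ± 0.16 and 1.09 ± 0.18 (adjusted p from 3.88e-12 to 4.31e-05). Mdm2, the p53 ubiquitin ligase, rose by 1.67 ± 0.06, 1.55 ± 0.06, 1.79 ± 0.06 and 0.97 ± 0.07. Cxcl10, an interferon-induced chemokine, rose by 2.21 ± 0.20, 5.35 ± 0.14, 2.4 ± 0.09 and 1.57 ± 0.10, and Trp53inp1, a p53 target, by 3.09 ± 0.10, 2.78 ± 0.11, 3.02 ± 0.11 and 1.92 ± 0.11. Ung, the uracil DNA glycosylase, fell in each line (−1.64 ± 0.11, −1.35 ± 0.12, −1.65 ± 0.11 and −1.53 ± 0.11). Trp53 itself passed in the ATM knock-out alone (0.19, adjusted p = 0.0116), a call that was lost in 3 of 4 fits without a library (0.18 to 0.20). At 4 h Cdkn1a had passed in wtATM alone (0.41 ± 0.12, adjusted p = 0.0417), and that call was lost in each of the 4 fits without a library (0.34 to 0.50).

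Of 35 p53 targets, 28, 29, 31 and 21 rose at 24 h and 1, 1, 1 and 3 fell (30, 30, 32 and 22 higher over the list alone; adjusted p between 1.07e-45 and 1.03e-09, medians 0.72, 0.88, 0.77 and 0.39). Of 40 interferon-stimulated genes, 32, 28, 32 and 29 rose and 0, 0, 2 and 0 fell (33, 29, 32 and 31 higher over the list alone; medians 1.51, 1.21, 1.23 and 0.84). Among their leading members were Tap1, a peptide transporter (2.07 ± 0.13 in wtATM), and Ifit1 (2.82 ± 0.14 in the ATM knock-out). Lysosome and autophagy genes rose in wtATM and the ATM knock-out (23 and 26 of 30 higher, 25 and 26 over the list alone), with Tpp1 and Grn in the lead (0.88 ± 0.06 and 0.77 ± 0.07 in wtATM). In wtATMIN, 12 rose and 2 fell (14 and 2 over the list alone; adjusted p = 0.247 with an estimated correlation). In the ATMIN knock-out the list passed only with library size as the scaling (adjusted p = 0.0199). NF-kB genes rose in the ATM knock-out and wtATMIN (18 and 16 of 28 higher, 1 and 4 lower; 19 and 17 higher over the list alone), with Ccl7, a chemokine, at 2.18 ± 0.13 in the ATM knock-out. Recombination and Fanconi genes rose in wtATMIN and the ATMIN knock-out (18 and 24 of 35 higher, 2 and 1 lower; 20 and 24 higher over the list alone; wtATMIN adjusted p = 0.0498 with an estimated correlation), with Brca1 at 0.69 ± 0.07 and 0.97 ± 0.08.

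G2/M genes, lower at 4 h, were higher at 24 h in wtATMIN (35 of 42, 36 over the list alone; adjusted p = 2.34e-19) and the ATMIN knock-out (30 higher and 1 lower, the same over the list alone; adjusted p = 4.73e-12). The list passed in neither wtATM (7 higher, 16 lower) nor the ATM knock-out (3 higher, 12 lower). Replication and E2F genes were lower in wtATM (23 of 47, 3 higher, the same over the list alone; adjusted p = 1.02e-05) and higher in the ATMIN knock-out (27, 4 lower; 29 and 5 over the list alone; adjusted p = 8.31e-08). Uhrf1 was at −0.80 ± 0.07 in wtATM and Rrm2 at 0.84 ± 0.06 in the ATMIN knock-out. Cholesterol synthesis genes remained lower by test in each line (14, 9, 11 and 20 of 25; 16, 9, 12 and 20 over the list alone), with adjusted p = 0.118, 0.394, 0.22 and 0.0153 with an estimated correlation. Integrated stress response genes passed as higher in wtATM, the ATM knock-out and wtATMIN (10, 14 and 11 of 30 higher, 6, 5 and 5 lower; 13, 15 and 12 higher over the list alone), with adjusted p = 0.25, 0.0658 and 0.188 with an estimated correlation. Matrix and fibroblast genes were lower in wtATMIN and the ATMIN knock-out (17 and 18 of 29, 2 and 2 higher; 20 and 19 lower over the list alone; adjusted p = 0.0898 and 0.117 with an estimated correlation), with Col3a1, a fibrillar collagen, at −1.28 ± 0.07 in wtATMIN.

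At 24 h 5309, 5160, 5331 and 5575 genes were called, with 2666, 2907, 2505 and 2648 higher. Library size alone gave 3131 higher and 1860 lower in wtATM, 3438 and 1900 in wtATMIN, and 3611 and 1911 in the ATMIN knock-out. The ATM knock-out count was 3346 without APH replicate 1. All 4 lines shared 495 rising and 579 falling genes, against 8.14 and 7.8 for independent lists. Called up in a line and down in another were 831 genes. Across 13928 genes the 24 h responses of wtATMIN and the ATMIN knock-out correlated at r = 0.574. Those of wtATM and the ATM knock-out correlated at r = 0.407, and those of lines from different pairs at r = 0.301 to 0.338. At 4 h the ATMIN pair was at r = 0.55, the ATM pair at r = 0.0702 and lines from different pairs at r = 0.216 to 0.278. All r are Pearson values, which extreme fold changes can move. By rank (Spearman) the 4 h values were 0.642 in the ATMIN pair, 0.23 in the ATM pair and 0.238 to 0.358 between pairs. The ATM knock-out APH 4 h libraries set apart above enter the 4 h values of that line. Genes are not independent replicates here.

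The 24 h response minus the 4 h response was then tested within each line. Mitosis genes were higher at 24 h relative to 4 h (29, 24, 41 and 42 of 42; 32, 24, 42 and 42 over the list alone), as were p53 targets (24, 24, 24 and 19 of 35; 25, 26, 25 and 21 over the list alone) and interferon-stimulated genes (16, 18, 25 and 17 of 40; 22, 20, 29 and 21 over the list alone). Lysosome genes were higher as well (19, 26, 18 and 15 of 30; 21, 28, 21 and 18 over the list alone). Replication and E2F genes were lower (18, 12, 26 and 16 of 47; 20, 14, 29 and 19 over the list alone). In the ATM knock-out that call had an adjusted p = 0.294 with an estimated correlation and was lost with library size alone (adjusted p = 0.206) or without APH 4 h replicate 1 (adjusted p = 0.0889). The numbers of genes called were 2794, 4058, 3430 and 3902, with 1455, 2230, 1685 and 1993 higher. Library size alone gave 3182 higher and 992 lower in the ATM knock-out, 2210 and 1080 in wtATMIN, and 2538 and 1284 in the ATMIN knock-out. The ATM knock-out count was 2658 without DMSO 24 h replicate 2 and 1817 with the compared groups alone. In DMSO alone 4278 genes were higher and 4301 lower at 24 h than at 4 h in wtATM. Time in culture and any library batch cannot be told apart in these DMSO counts. A shift shared by the DMSO and APH samples of a time point cancels in the difference of responses.

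The ATM knock-out line and wtATM differed in a large part of the transcriptome: 10195, 10884, 10965 and 11338 genes were called in DMSO 4 h, APH 4 h, DMSO 24 h and APH 24 h. Of these, 3325 were higher and 3280 lower in all 4 conditions. Over 8 libraries per line, Syndig1, a synapse protein, was at 28.6 ± 3.96 CPM in the knock-out line and had 0 reads in wtATM (at least 1200-fold higher). The Y-linked helicase Ddx3y was at 99.9 ± 37.4 against 0.0672 CPM, and Chst10, a sulfotransferase, had 1 read in wtATM (3070-fold higher; 95% counting interval 551 to 121000). Lower in the knock-out line were Dlx3, a homeobox gene (25.4 ± 10.8 CPM in wtATM, 1 read in the knock-out; 2940-fold, 528 to 116000), Dapk1, a death-associated kinase (20.4 ± 4.31 CPM, 1 read; 2370-fold, 425 to 93500), and Nrg2, a neuregulin (13.3 ± 2.83 CPM, 0 reads; at least 513-fold). The myogenic factor Myf5 was at 21.4 ± 3.34 CPM in wtATM with 2 reads in the knock-out line (1240-fold, 344 to 10300), and the CDK inhibitor Cdkn2b at 30.7 ± 8.54 against 0.0486 CPM. Among the fixed genes, Mdm2 was lower by −1.50, −1.26, −1.41 and −1.54, Cdkn1a by −0.91, −1.23, −0.83 and −1.07, and Trp53 was higher by 0.49, 0.39, 0.49 and 0.82.

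Of 35 p53 targets, 26, 23, 25 and 25 were lower in the ATM knock-out line and 3, 4, 3 and 5 higher (27, 23, 25 and 25 lower over the list alone; adjusted p between 1.31e-07 and 7.39e-05). The list was led by Perp, a desmosome and apoptosis gene (278.7 CPM in wtATM and 5.93 in the knock-out line). Perp and Mdm2 lie on chromosome 10, whose genes had a median of −0.59 in this pair in DMSO at 4 h. In DMSO wtATMIN was lower than wtATM on this list too (given below), so the direction is not particular to the knock-out line. Posterior Hox genes were higher (11, 11, 13 and 13 of 18, with 5, 3, 3 and 3 lower, and 5, 4, 3 and 3 lower over the list alone), with Hoxd13 at 38.4 ± 4.73 against 0.0474 CPM. Epithelial markers were lower by test (5, 4, 4 and 4 of 10, with 1, 1, 2 and 4 higher; 1, 1, 2 and 5 higher over the list alone), with the keratin Krt14 at 0.403 CPM against 137.9 in wtATM. Muscle markers passed as lower (6, 3, 5 and 4 of 9, 1, 0, 0 and 0 higher, the same over the list alone; adjusted p = 0.0407, 0.061, 0.0743 and 0.0892 with an estimated correlation). Neural markers passed as higher (4, 3, 4 and 5 of 7, 2, 1, 1 and 1 lower, the same over the list alone; adjusted p = 0.0418, 0.109, 0.0498 and 0.0588 with an estimated correlation). The APH 4 h call was lost without ATM knock-out APH replicate 1 (adjusted p = 0.0726) or 2 (adjusted p = 0.0514). Sox2, a stem cell transcription factor, was at 53.8 against 12.4 CPM. Against wtATM, wtATMIN was likewise lower for epithelial and higher for neural markers in DMSO. Of 6 sex-linked genes 4 were higher, 4 over the list alone, in each condition (adjusted p from 1.37e-09 to 2.49e-07). Replication and E2F genes were higher (28, 35, 26 and 36 of 47; 30, 35, 26 and 36 over the list alone), with adjusted p = 0.182, 0.0591, 0.373 and 0.0289 with an estimated correlation. The DMSO 24 h call was lost with library size alone (adjusted p = 0.0758). Blood and endothelial markers passed in none of the 28 comparisons (smallest adjusted p = 0.077 and 0.382), and the adipocyte markers held 4 tested genes.

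The ATMIN knock-out line and wtATMIN differed at 8304, 7777, 9174 and 9350 genes in the same order of conditions, with 2104 higher and 2442 lower in all 4. Over 8 libraries per line, Xist, the X-inactivation transcript, was at 818 ± 283 against 0.692 CPM, and Tsix, its antisense partner, at 51.8 ± 13.1 against 0.0509 CPM. Without a stated strand setting their reads cannot be told apart. Rpl39l, a ribosomal protein gene, was at 11.2 CPM against 1 read in wtATMIN (1580-fold, 283 to 62300). Fabp4, a fatty acid binding protein, was at 76.5 ± 19.9 against 0.924 CPM. Lower in the knock-out line was Ifi202b, an interferon-inducible gene (21.5 ± 12.2 CPM in wtATMIN, 2 reads in the knock-out; 1450-fold, 402 to 12000). The Y-linked genes Ddx3y (39.5 ± 12.3 against 0.0912 CPM) and Kdm5d (17.5 against 0.0654 CPM) were lower as well. Xist and Y-linked transcripts thus went in opposite directions in this pair. The ATM pair differed in Y-linked transcripts too. Among the fixed genes Mdm2 was lower by −0.28, −0.42, −0.47 and −1.29, Trp53 by −0.31, −0.37, −0.25 and −0.44, and Dynll2, the paralog of Dynll1, was higher by 0.52, 0.63, 0.54 and 0.40.

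Matrix and fibroblast genes were higher in the ATMIN knock-out line (21, 22, 19 and 19 of 29, with 5, 5, 7 and 7 lower; 21, 22, 20 and 19 higher over the list alone), with adjusted p = 0.015, 0.012, 0.176 and 0.135 with an estimated correlation. Col3a1 was at 1721 ± 359 against 219.6 ± 202 CPM. Lysosome and autophagy genes were higher (20, 19, 19 and 16 of 30, with 4, 3, 3 and 3 lower; 20, 19, 19 and 16 higher over the list alone; adjusted p between 2.68e-08 and 1.66e-06), led by the protease Ctsl (1.86, 1.91, 2.46 and 2.09). Neural markers were lower (3, 3, 4 and 4 of 7; 4, 3, 4 and 4 over the list alone; adjusted p = 0.00523, 0.00321, 0.0422 and 0.0795 with an estimated correlation), with Tubb3 at −3.33 ± 0.13. NRF2 targets passed as lower in DMSO 4 h, DMSO 24 h and APH 24 h (11, 12 and 11 of 22, with 6, 6 and 6 higher; 11, 12 and 12 lower over the list alone), with adjusted p = 0.441, 0.34 and 0.294 with an estimated correlation. Gsr, glutathione reductase, was at −1.13 ± 0.06. It lies on chromosome 8, whose genes had a median of −0.78 between these lines in DMSO at 4 h. List members on that chromosome were not tested apart. Integrated stress response genes were higher in DMSO at 24 h (20 of 30, 21 over the list alone; adjusted p = 1.18e-07), with the pseudokinase Trib3 at 3.20 ± 0.12. NF-kB genes were higher with APH at 4 h (17 of 28, 4 lower, the same over the list alone; adjusted p = 0.000166) and lower with APH at 24 h (17, 7 higher, the same over the list alone; adjusted p = 0.0504 with an estimated correlation), where Cxcl5 was at −5.26 ± 0.20.

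**Figure D4:**
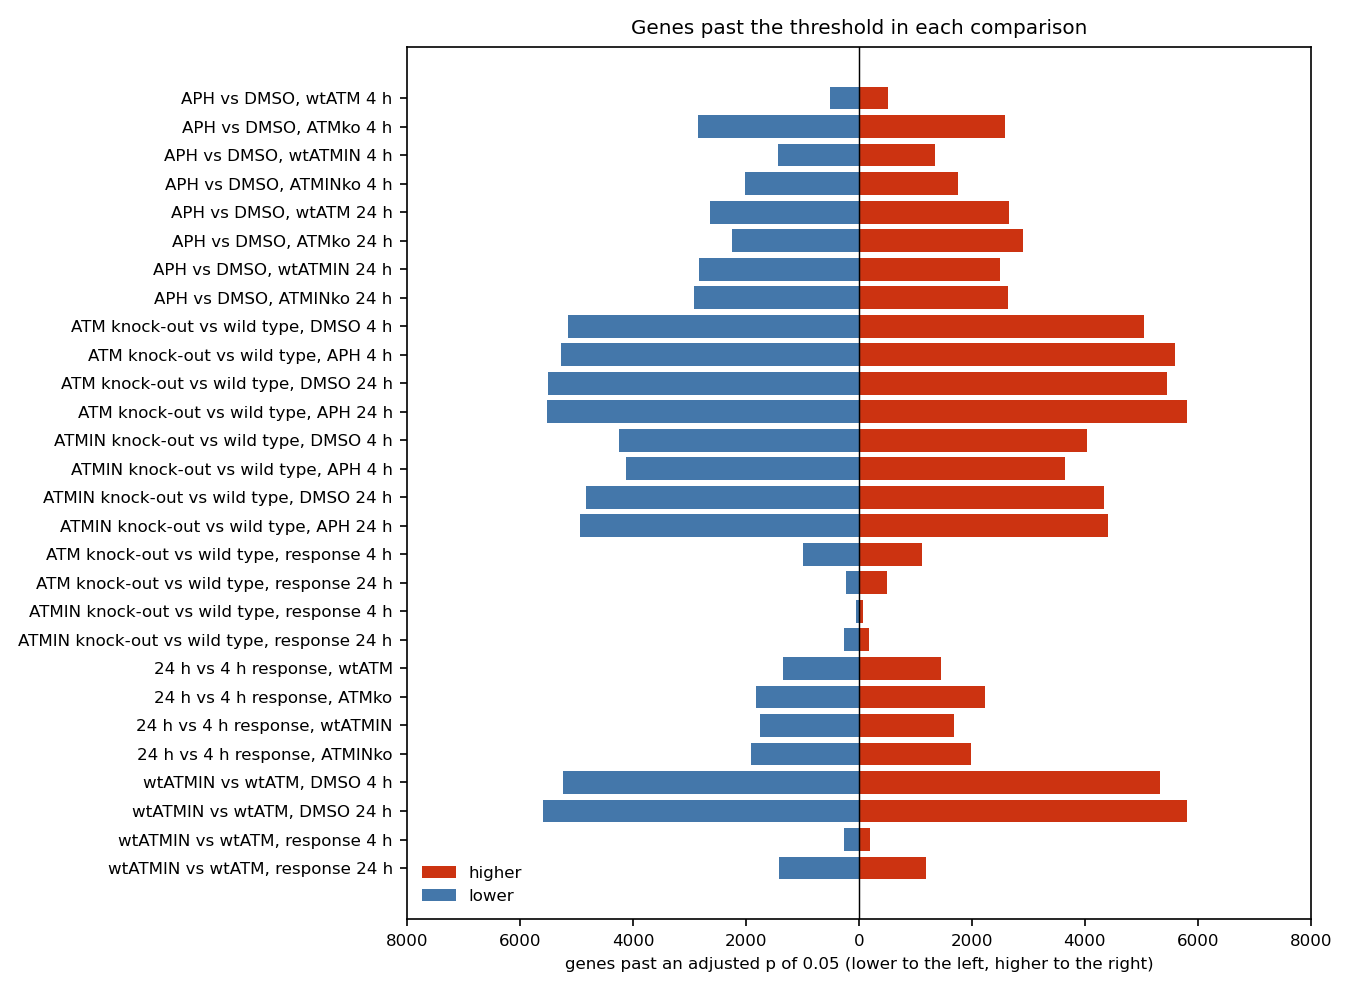
Number of genes past an adjusted p of 0.05 (horizontal axis), higher to the right and lower to the left, in each of the 28 comparisons (vertical axis). The wild-type lines differ from each other in DMSO at 10569 and 11407 genes, more than either knock-out from its wild type in the same condition.

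Calls in all 4 conditions overlapped between the knock-outs mostly in opposite directions. The number higher in the ATM and lower in the ATMIN knock-out was 776, where independent lists would share 439.3 (Fisher's exact p = 1.98e-71), and the number lower in ATM and higher in ATMIN was 642 against 373.4 (Fisher's exact p = 1.13e-52). Higher in both were 415 genes against 378.5 (Fisher's exact p = 0.0299), and lower in both 433 against 433.3 (Fisher's exact p = 1). These overlap p-values treat genes as independent, but genes of a chromosome shifted together. In DMSO at 4 h the medians were 0.28 (ATM pair) and −0.78 (ATMIN pair) on chromosome 8, and 0.39 and 0.21 on chromosome 18. The overlap was not tested with chromosome medians taken off, and genotype cannot be told apart from line. Within 10 Mb of Atm, 85 of 216 genes (39.4%) differed in all 4 conditions against 36% of the other genes (Fisher's exact p = 0.319). Within 10 Mb of Atmin the count was 104 of 243 (42.8%) against 24.6% elsewhere (Fisher's exact p = 7.88e-10). The rest of chromosome 8 had a higher share still (411 of 722, 56.9%; Fisher's exact p = 0.000148 within the chromosome).

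The wild-type lines differed from each other in DMSO at 10569 genes at 4 h (5324 higher in wtATMIN) and 11407 at 24 h (5817 higher). Library size alone moved the median of all genes by 0.11 at 24 h and gave 6653 higher and 4532 lower. Stmn2, a neuronal tubulin-binding protein, was at 51.7 ± 38.2 CPM in wtATMIN and had 1 read in wtATM over 8 libraries each (6490-fold, 1160 to 256000). Dio3, a deiodinase, was at 33.8 ± 26.3 CPM against 2 reads (2120-fold, 588 to 17500). Lower in wtATMIN were Krt6a, a keratin (223 ± 110 against 0.201 CPM), and Ms4a4d (14.3 ± 7.01 CPM against 0 reads; at least 671-fold). Of 35 p53 targets 22 and 24 were lower in wtATMIN at 4 h and 24 h and 5 and 5 higher (the same over the list alone; adjusted p = 1.55e-10 and 2.02e-12). Cdkn1a was at −2.30 ± 0.14 and −2.89 ± 0.16, and Mdm2 at −2.02 ± 0.06 and −2.11 ± 0.06. Neural markers were higher (5 and 5 of 7, the same over the list alone) and epithelial markers lower (4 and 4 of 10, with 2 and 2 higher, the same over the list alone; adjusted p = 0.0077 and 0.00651 with an estimated correlation).

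The APH response of the ATM knock-out line was compared with that of wtATM. At 24 h NF-kB genes responded more in the knock-out line (14 of 28 higher and 0 lower, 17 over the list alone; adjusted p = 1.1e-22), led by Il1rl1, an interleukin receptor (0.91 ± 0.10), Nfkb2 (0.72 ± 0.09), Ccl7 (2.49 ± 0.34) and the inhibitor Nfkbia (1.01 ± 0.14). Replication and E2F genes responded less negatively (14 of 47 higher and 0 lower, 28 over the list alone; adjusted p = 3.07e-19), with Cdc6, a replication licensing factor, at 0.91 ± 0.10. Krt16, a keratin, went from 0 reads to 5.50 ± 0.338 CPM in the knock-out line and from 17.4 ± 0.587 to 11.4 ± 0.106 CPM in wtATM. Celf5, an RNA-binding protein gene, rose from 2.06 ± 0.201 to 21 ± 2.4 CPM in wtATM and from 4.02 ± 0.588 to 7.27 ± 0.238 CPM in the knock-out line (−2.49 ± 0.28). The responses of Cdkn1a (−0.24 ± 0.18, adjusted p = 0.587) and Mdm2 (−0.13 ± 0.09, adjusted p = 0.522) did not pass as different. Atm itself differed in response (0.84 ± 0.21, adjusted p = 0.0224), but the call was lost in 7 of 8 fits without a library (0.71 to 0.99) and with library size alone. At 24 h 724 genes were called, 496 of them higher. The count was 366 to 427 without any 1 library but wtATM APH replicate 2 (728). With RLE size factors the share higher was 57.2% against 68.5%.

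At 4 h 2101 genes responded differently between the ATM knock-out line and wtATM, 1112 higher and 989 lower. With the spread taken from the 8 compared libraries alone only 4 genes passed, and the calls of Chek1, H2afx and Rpph1 below were lost. Replication histones were higher in this comparison (20 of 44, 25 over the list alone; adjusted p = 0.247 with an estimated correlation), with Hist1h1d at 2.74 ± 0.38, but not without ATM knock-out APH replicate 1 (6 higher, 1 lower; adjusted p = 0.194). Mitosis genes were higher (13 of 42, 2 lower; 21 higher over the list alone; adjusted p = 0.129 with an estimated correlation) and immediate-early genes lower (8 of 25, 13 over the list alone; adjusted p = 0.137 with an estimated correlation), with Cyr61 at −0.64. Chek1 was at 1.03 ± 0.17 (adjusted p = 0.000326) and H2afx at −0.74 ± 0.15 (adjusted p = 0.00167). Rpph1, the RNA of ribonuclease P, went from 10.7 to 111 ± 56.3 CPM in the knock-out line and from 54.8 ± 62.3 to 9.30 CPM in wtATM. It was highest in wtATM DMSO replicate 1 and ATM knock-out APH replicate 1 (90.1 and 128 CPM), the libraries with the most Gm42418 (37651 and 83079 CPM), so its change cannot be told apart from library content. Its call was lost without wtATM DMSO replicate 1 (3.58). Without 1 library the count was 875 and 1288 (wtATM DMSO replicates 1 and 2), 734 (wtATM APH replicate 2), 568 (ATM knock-out DMSO replicate 2), 4813 and 654 (ATM knock-out APH replicates 1 and 2). Library size alone gave 553 higher and 2291 lower, with the median of all genes moved by −0.10. With it p53 targets (6 of 35 higher, 8 over the list alone) were no longer called (adjusted p = 0.0872; 0.153 with an estimated correlation). That call was also lost without ATM knock-out APH replicate 1 (adjusted p = 0.074).

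The ATMIN knock-out line responded to 24 h of APH with a smaller rise of p53 target genes than wtATMIN. Of 35 targets 10 had a lower response and 0 a higher (19 lower and 2 higher over the list alone; adjusted p = 7.82e-20). Mdm2 rose from 62.4 ± 0.334 to 215.5 ± 7.80 CPM in wtATMIN and from 45.1 ± 2.03 to 88.4 ± 2.30 CPM in the knock-out line (difference −0.82 ± 0.09, adjusted p = 4.27e-07). Cdkn1a rose from 6.16 ± 0.797 to 32.8 ± 0.74 and from 6.75 ± 1.86 to 14.4 ± 0.277 CPM (−1.31 ± 0.25, adjusted p = 0.00309), a call that was lost without ATMIN knock-out DMSO replicate 1 (−0.99). Interferon-stimulated genes also responded less (10 of 40 lower and 1 higher, 12 and 4 over the list alone; adjusted p = 1.25e-09), led by Ccl5, a chemokine (8.34 ± 0.0112 to 39.5 ± 0.901 CPM in wtATMIN, 59.5 ± 2.02 to 91.3 ± 0.529 CPM in the knock-out line). NF-kB genes (6 of 28 lower, 9 over the list alone; adjusted p = 1.55e-10) and integrated stress response genes (6 of 30 lower, 9 over the list alone; adjusted p = 1.85e-12) were lower too. Trib3 rose from 6.75 ± 0.517 to 26.3 ± 0.0423 CPM in wtATMIN and went from 62.5 ± 1.85 to 46.2 ± 0.0113 CPM in the knock-out line.

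Replication and E2F genes responded more in the ATMIN knock-out line at 24 h (11 of 47 higher and 0 lower, 28 over the list alone; adjusted p = 1.41e-20), with the primase subunit Prim2 at 0.81 ± 0.12. Igfbp5, an IGF-binding protein, went from 5.08 to 0.525 CPM in wtATMIN and from 3.29 to 1.49 CPM in the knock-out line (2.09 ± 0.41). Hist1h2bc, a histone gene that can share reads with paralogs, went from 11.4 to 27.4 CPM and from 12 to 3.57 CPM (−3.02 ± 0.22). Dynll1 was at 0.56 ± 0.10 (adjusted p = 0.000988). At 24 h 450 genes were called, 187 higher and 263 lower, and 1514 with the spread taken from the compared groups alone. The count was 219 to 268 without any 1 library but wtATMIN DMSO replicate 1 (319).

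**Figure D5:**
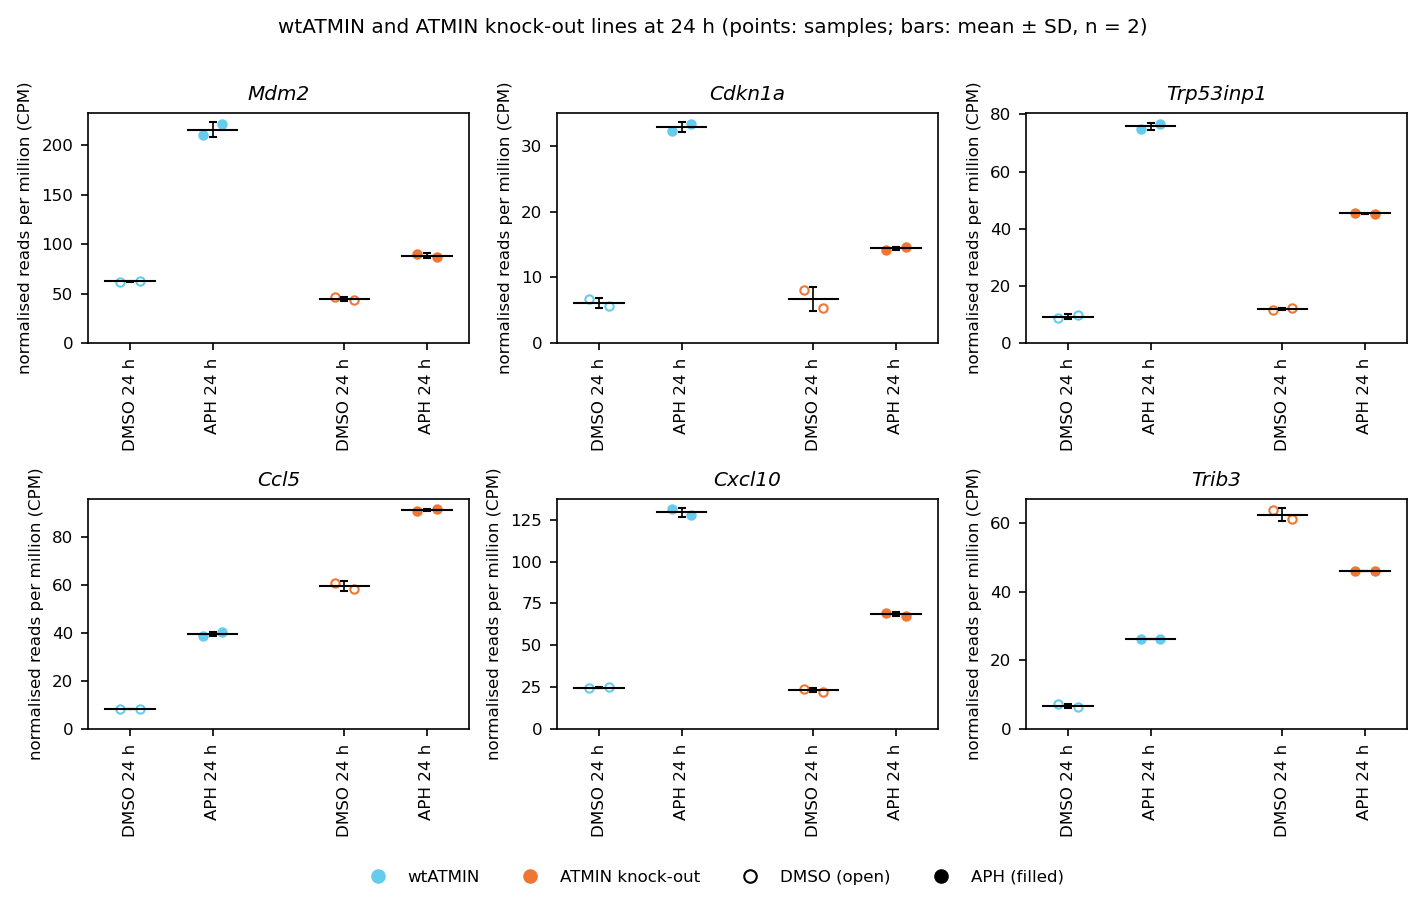
Normalised CPM (vertical axes) of 3 p53 targets (Mdm2, Cdkn1a, Trp53inp1), Ccl5, Cxcl10 and Trib3 in the 8 libraries of the ATMIN pair at 24 h (horizontal axes); bars give mean and SD of 2 samples. With APH, Mdm2 reaches 215.5 CPM in wtATMIN and 88.4 CPM in the knock-out line.

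At 4 h the ATMIN knock-out line responded with a larger rise of NF-kB genes (7 of 28 higher and 0 lower, 12 over the list alone; adjusted p = 4.16e-27). The chemokine Cxcl1 went from 17.9 ± 0.571 to 36.4 ± 1.63 CPM in the knock-out line and from 45.4 ± 2.37 to 23.8 ± 3.16 CPM in wtATMIN (1.95 ± 0.14). Ccl2 went from 17.0 ± 0.19 to 76.4 ± 1.01 and from 9.59 ± 2.92 to 12.8 ± 3.02 CPM (1.76 ± 0.21). Dio3, a deiodinase, fell in wtATMIN from 33.9 ± 9.37 to 9.22 CPM and was at 3.50 ± 0.0958 and 4.04 ± 0.627 CPM in the knock-out line (2.10 ± 0.30). Mitosis genes responded more negatively (4 of 42 lower, 19 over the list alone; adjusted p = 2.37e-15), with Cenpf, a kinetochore protein, at −0.88 ± 0.17. At 4 h 124 genes were called, 64 higher and 60 lower. The count was 54 to 81 without any 1 library but wtATMIN DMSO replicate 1 (156).

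The APH responses of the wild-type lines also differed, at 451 genes at 4 h (192 higher in wtATMIN) and 2605 at 24 h (1189 higher). At 24 h mitosis genes responded more in wtATMIN (30 of 42 higher and 0 lower, 35 over the list alone; adjusted p = 1.04e-26), with Troap, a spindle protein, at 1.07 ± 0.11. Matrix and fibroblast genes responded more negatively (15 of 29 lower, 18 over the list alone; adjusted p = 9.36e-13), with Col3a1 at −1.29 ± 0.10. The 4 h count was 164 to 290 without any 1 library but wtATMIN DMSO replicate 1 (548), and library size alone gave 93 higher and 302 lower.

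The size of the response was compared on genes chosen for their APH response in the other pair of lines. The 1499 genes that rose at 24 h in both lines of the ATM pair had a median of 0.26 in wtATMIN and 0.26 in the ATMIN knock-out (adjusted p = 0.392 by camera over 8 such tests). The 1472 that rose in both lines of the ATMIN pair had medians of 0.28 in wtATM and 0.29 in the ATM knock-out (adjusted p = 0.58). Of the 8 tests by camera the smallest adjusted p was 0.118. Fry, without adjustment, called the 1472 genes as responding more in the ATM knock-out line (median difference 0.031). Of these, 77 had a higher called response there and 33 a lower. It also called the 1370 genes that fell at 24 h in both lines of the ATM pair as lower in the ATMIN knock-out (median difference −0.032). The other sets did not pass by fry. A response of equal size in both lines of a pair was therefore not shown. In each of the 10 tables that the authors deposited, fewer genes had an adjusted p under 0.05 than were called here among the same genes. Genes called in both had the same direction in each table. For the ATM knock-out in DMSO at 4 h the authors' table had 7979 genes, with 9371 called here and 7875 called in both. For the ATM knock-out with APH at 4 h the numbers were 7288, 10072 and 7277. For APH in wtATMIN they were 1975, 2760 and 1840 at 4 h and 5059, 5296 and 4488 at 24 h.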

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

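Tests chosen only after the result was seen were those of separately derived lines, of a response smaller for all genes, of a higher DMSO level at 24 h and 4 h, of library scaling, of a few genes taking the counts, of flanking sequence after taking off bin medians, and of the spread within the compared groups. The differences between APH responses are given here because a test of the difference itself passed. Such genes numbered 2101 and 724 for the ATM knock-out at 4 h and 24 h, 124 and 450 for the ATMIN knock-out, and 451 and 2605 between the wild-type lines. The 24 h and 4 h responses differed at 2794, 4058, 3430 and 3902 genes in wtATM, the ATM knock-out, wtATMIN and the ATMIN knock-out.

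Among the named genes, F5 (8.86), Slc6a17 (7.12), Pstpip2 (−6.03) and Tcea3 (−5.92) had the largest and smallest log2 differences in response for ATM at 4 h. Groups without a read enter each of these comparisons, so the fitted values depend on the prior count, and each call was lost in at least 3 of 8 fits without 1 library (F5 from 7.42 to 9.77, Slc6a17 from 1.92 to 9.48, Pstpip2 from −6.50 to −5.30, Tcea3 from −6.23 to −5.38). For ATM at 24 h they were Krt16 (10.08), Pmaip1 (5.73), Ripk4 (−4.06) and Tspan13 (−3.36), of which Krt16 alone passed in each of the 8 fits without 1 library; the others ran from 4.78 to 6.32, −4.35 to −3.83 and −5.57 to −2.56. A group with 0 to 2 reads enters each of these 4 comparisons, so these values and ranges depend on the prior count as well. For ATMIN at 4 h they were Dio3 (2.10), Il15ra (2.00), Lncenc1 (−5.39) and Syt17 (−3.08), of which Dio3 and Syt17 passed in each of the 8 fits. Il15ra and Lncenc1 were lost in 7 of 8 (1.86 to 2.15 and −5.64 to −5.13), and Lncenc1 had 0 reads in wtATMIN DMSO 4 h. For ATMIN at 24 h they were Casz1 (2.65), Lgr6 (2.14), Hist1h2bc (−3.02) and Hist1h2ac (−2.98). Both histone calls passed in each of the 8 fits, Casz1 was lost without ATMIN knock-out DMSO replicate 1 (2.21), and Lgr6 was lost in all 8 (2.03 to 2.27).

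The larger number of differing responses for ATM at 4 h was weighed against its libraries. Over the 2101 called genes, the median difference in the called direction was set against its value with all libraries. It was 0.757 of that value without ATM knock-out APH replicate 2, and 1.29 of it without replicate 1. These genes were called with both libraries in the fit, and the other compared libraries stay in it. The ratios therefore cannot tell how far a single library decides the calls. A few genes taking the counts would move all others by a common amount. The median size of the called differences was 5.51 times the shift of all genes between library size and TMM. That ratio cannot decide, because only genes past the threshold enter it. Refitted without the most abundant genes of the ATM knock-out APH 4 h libraries, the comparison gave 2207 calls. The count with TMM thus did not rest on those genes. A larger spread between these libraries than between others may account for the count, since only 4 genes passed when the spread came from the 8 compared libraries, while the count of 2101 rests on the spread shared by all groups. A dependence of the early response on ATM stays open and was not tested apart from the line.

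The genes that differ in all 4 conditions between a knock-out and its wild type are consistent with separately derived lines, as the wild-type lines differed from each other at 1.04 times as many genes as the larger knock-out count in DMSO at 4 h. Copy number of whole chromosomes does not account for most of them: at least 75% still differed after the median of their chromosome was taken off. Flanking sequence of the strain used for targeting would raise the share of differing genes near Atmin. Within 10 Mb calls were instead fewer than on the rest of the chromosome (Fisher's exact p = 0.000148). Most were lower (101 of 104 near Atmin and 402 of 411 on the rest), as genes of the whole chromosome were, so that shift enters this comparison. After the median of each 20 Mb bin was taken off, 14.8% of genes differed within 10 Mb against 25.8% (Fisher's exact p = 0.000402). Shares with bin medians taken off are likewise not shares of called genes. No excess was thus seen within 10 Mb of Atmin, but a share cannot exclude an effect on single genes there. Within 5 Mb flanking sequence stays open (18.8% against 23.3%, Fisher's exact p = 0.446). For ATM it stays open, because the answer depends on the window: with bin medians taken off, 41.7% of genes differed within 10 Mb against 36.6% on the rest of the chromosome (Fisher's exact p = 0.176), and 43.8% within 20 Mb against 33.9% (Fisher's exact p = 0.00254). The loss of ATM or ATMIN itself stays open, since 1 line per knock-out leaves no second line to compare.

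The smaller rise of p53 target and interferon-stimulated genes in the ATMIN knock-out line at 24 h was weighed against other explanations. A smaller response of all genes is argued against by the 1499 rising genes chosen in the ATM pair. Their medians had a ratio of 1.01 (knock-out over wild type). Of these, 700 were called as rising in wtATMIN and 687 in the knock-out line. The response was called lower in the knock-out line for 76 and higher for 30, so a smaller response of a part of them stays open. Library scaling, which moves all genes of a library alike, was argued against, since the members' median minus that of all other genes was −0.4208 (log2). A higher starting level is argued against as the whole cause for the p53 targets as a list: in knock-out DMSO at 24 h their median difference was 0.0064 (quartiles −0.5076 and 0.2555), under the 0.4431 it would need. With APH at 24 h it was −0.3433. For the 10 p53 targets called with a smaller rise, which these libraries helped to choose, a part of it stays open, with a DMSO median of 0.3120 (8 of 10 higher) beside a median difference in response of −0.9569. For interferon-stimulated genes it could account for the smaller rise, with a median of 0.5077 in DMSO (29 of 40 higher), but these DMSO libraries are part of the compared difference. Whether that level also holds at 4 h stays open: the DMSO median there was −0.1799, but the upper quartile of 0.3588 reaches the 0.3429 needed. An effect of ATMIN on p53 or interferon signalling stays open as a hypothesis, as does the line.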

How the results depend on the processing

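Tests chosen after the data were seen were those without the ATM knock-out line, without either of its APH 4 h libraries, without the most abundant genes of these libraries, and after taking off the medians of chromosomes or 20 Mb bins. The side with more calls changed in 8 of 28 comparisons with library size alone and in 4 with RLE. With library size alone the ATM interaction at 4 h went from 1112 higher and 989 lower to 553 and 2291, and APH at 24 h from 2505 and 2826 to 3438 and 1900 (wtATMIN) and from 2648 and 2927 to 3611 and 1911 (ATMIN knock-out). Without ATM knock-out APH replicate 1 the ATM interaction at 4 h had 2130 higher and 2683 lower. Fitting the compared groups alone gave 1136 genes for APH in the ATM knock-out at 4 h, 4 for the ATM interaction at 4 h, 1514 for the ATMIN interaction at 24 h, 1817 for 24 h against 4 h in the ATM knock-out, and 49 rising and 96 falling genes shared at 4 h. No filter gave 225 for the ATMIN interaction at 4 h, library size alone 292 falling genes shared at 24 h, and the 3 lines without the ATM knock-out 188 and 259 shared at 4 h. List calls numbered 247, 122 with an estimated correlation, 380 with fry, 279 without a filter and 245 with RLE or library size. Before adjustment, transferred genes gave p = 0.00628 with library size (rising, ATM 4 h), and 0.378 (rising, ATMIN 4 h) and 0.123 (falling, ATMIN 24 h) with an estimated correlation. Adjusted over the 8 tests these were 0.0502, 0.547 and 0.547, and none of the 3 passed with TMM (0.222, 0.118 and 0.118). Fry, without adjustment, passed for transferred genes at 24 h where adjusted camera did not, as given above. The cause of these differences was not tested.

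Without 1 library the counts ran from 528 to 690 (APH 4 h, wtATM), 2392 to 6786 (ATM knock-out), 1408 to 2722 (wtATMIN) and 2270 to 2604 (ATMIN knock-out), from 3618 to 4074, 3346 to 3566, 3605 to 3855 and 3810 to 4028 at 24 h, from 568 to 4813 and 366 to 728 (ATM interaction, 4 h and 24 h), 54 to 156 and 219 to 319 (ATMIN interaction), 2658 to 5649 (24 h against 4 h, ATM knock-out) and 164 to 548 (wild-type interaction, 4 h). Calls of named genes were lost 364 times and gained 31 times without 1 library, and lost 22 times and gained 6 times with DESeq2. The replicate number as a block gave 246 list calls against 247, ended 9 calls of named genes and added 4, and moved no count by over 1.5 times. Deviations of same-numbered samples correlated between groups with no common sign. The correlations ran from −0.237 to 0.241 at 4 h (median 0.0279) and −0.297 to 0.177 at 24 h (median 0.0185). The labels do not say whether such samples share a culture, day or batch, and these values cannot settle it.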

Other observations

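The test of a change in the ATMIN knock-out line rather than in wtATMIN was chosen only after the result was seen. Sex-linked transcripts split the lines across genotypes. The Y-linked Uty was at 27.4 CPM in the ATM knock-out line with 1 read in wtATM, and at 12.7 CPM in wtATMIN with 3 reads in the ATMIN knock-out line. Thy1, a fibroblast surface protein, was at 232.5 ± 33.3 CPM in the ATM knock-out line and 0.342 CPM in wtATM (SD, 8 libraries per line). Hoxd13, a posterior Hox gene, was at 11.2 ± 6.55 CPM in wtATMIN and 0.0451 CPM in the ATMIN knock-out line.

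Genes of chromosome 8 were lower in the ATMIN knock-out line than in wtATMIN in DMSO at 4 h, with a median log2 difference of −0.78. A copy number difference of the whole chromosome is a candidate explanation, as each 20 Mb bin had a median of −0.52 or lower. Which line changed stays open: against wtATM the medians on this chromosome were 0.77 in wtATMIN, 0.28 in the ATM knock-out and −0.02 in the ATMIN knock-out, so wtATM is no plain baseline. Atmin lies on this chromosome, and its difference of −2.41 was larger than the median. On chromosome 10 the medians against wtATM were −0.59 in the ATM knock-out, −0.68 in wtATMIN and −0.53 in the ATMIN knock-out. Copy number was not measured here.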
